A study of Rattus norvegicus with 24 samples.

How the data were processed

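The samples were brain tissue of male Wistar rats, 10 weeks old, given saline or MK-801, a drug that blocks the open channel of the NMDA type of glutamate receptor. Per the labels, 3 rats received saline and 6 received MK-801 in 2 dose groups, 0.08 mg per kg (low dose) and 0.16 mg per kg (high dose), by injection into the abdomen, and brains were taken 40 min later. The 6 dissected regions were midbrain, amygdala, ventral striatum, cerebral cortex, hippocampus and hypothalamus. Total RNA was isolated with a column kit, amplified and labelled with Cy3 and Cy5, and each array held MK-801 RNA in 1 dye and saline RNA in the other. The 24 arrays were 12 dye swaps, that is 2 arrays with exchanged dyes for each of the 6 regions and 2 doses. The labels name no animal for an array and do not say whether RNA of several rats was pooled, so a dye swap counted as 1 value. An electrophysiological part of the study is not analysed here.

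The deposited scanner files came from Agilent Feature Extraction 9.5.3.1, 1 file per array, with 45018 spots, of which 43379 were not controls and belonged to 41012 probes. Per the file headers, each spot carried a mean and a background signal per colour as fluorescence intensity, flags for outlying, saturated and well measured spots, and a log ratio computed by the software after background subtraction, spatial detrending and dye normalization. The deposited value table of the series held the log10 ratio of Cy5 to Cy3 processed signals of each array. Comparison of the numbers showed that this table matched the scanner files within 5e-07 on 19 arrays and within 0.00413 on the 4 amygdala arrays and the first midbrain array at the high dose, was not turned for the dye swaps and was not centred, with array medians between -0.0295 and 0. The scanner file of that midbrain array, and no other, stored its values with 3 significant digits. The file dates placed the arrays on 3 scan days, with midbrain and amygdala on the first, ventral striatum and cerebral cortex on the second, and hippocampus and hypothalamus on the third. Each region lay on its own slide, so region, slide and region-specific saline RNA cannot be told apart.

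Analyses used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and matrixStats 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Signals were background corrected with the normexp method (offset 50) and normalized within each array by loess, and controls and spots with an outlier flag were left out. Spots of a probe were averaged, and ratios were turned so that each value is the log2 ratio of MK-801 to saline. A probe was kept if it was well above background in both colours on at least 12 of the 24 arrays, which 27690 probes were. A gene was represented by its probe with the highest mean intensity, and a regional value needed both arrays of the dye swap. This gave 23468 genes or transcripts, 20725 of them with values on all 24 arrays. Probes were named through the RefSeq gene table of assembly GRCr8, used for names only. Of the 41012 probes, 10861 matched by accession, 5542 by symbol and 3704 by synonym, and 20905 kept the name in the files. A gene symbol was had for 20182 probes and a chromosome, on assembly rn3 as in the files, for 38683. Transcripts without a symbol were counted and not named. Of the 605 genes called over both doses, 80 had several probes, and in 14 of those another probe had the opposite sign.

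Signal limited the precision. Between 56.3% and 79.1% of the probes were well above background in both colours of an array, and the median ratio of signal to background was 1.82 to 3.10 in Cy3 and 3.23 to 5.77 in Cy5. The standard deviation of the log2 ratios within an array was 0.140 to 0.249. At most 8 spots of an array were saturated. The 2 arrays of a dye swap correlated negatively across genes (r from -0.481 to -0.0755, genes not being independent replicates), and arrays of the same dye orientation correlated positively across different groups (median r 0.507). The dye effect of a probe had a median size of 0.07 on the log2 scale, and the change over both doses had a median size of 0.02. The number of arrays sets the precision of every value.

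Changes across regions were tested with limma (lmFit and eBayes, tested against 0) on 6 values, 1 per region, separately for the mean of both doses, the high dose, the low dose and the high minus low difference. P values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. These p values measure the spread between regions of the same 9 rats, not the spread between rats. A ratio tested against 0 leaves out the spread between saline rats, both doses were set against the same 3 saline rats, and a difference between sets of rats gives the same direction in every region. At least 4 of the 6 regional values were required, a limit set after a first look at the counts; genes with all 6 values only are an alternative in the closing section. Differences between regions were tested with limma's moderated F on 12 values (6 regions, 2 doses, dose as covariate) and by contrasts of each region with the mean of the other 5, adjusted for each contrast, both for genes with complete values. Their p values measure the spread between the 2 doses of a region, not the spread between rats. These 2 values share a slide and the same 3 saline rats, so they are not independent. Within a single region and dose there was 1 dye swap and no p value. There, genes were counted that passed 1.5-fold in the same direction on both arrays, beside the genes that passed it in opposite directions, which no treatment effect gives. The distribution of these genes over chromosomes was tested with two-sided Fisher's exact tests against all tested genes with a chromosome, adjusted over all 252 tests.

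The samples, comparisons, tests, main alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The 23 lists covered immediate early genes, glucocorticoid and stress responsive genes, NMDA receptor subunits, other glutamate receptors, GABA synthesis and receptors, heat shock and unfolded protein genes, ribosomal proteins, oxidative phosphorylation, choroid plexus, oligodendrocytes, astrocytes, microglia, endothelium and pericytes, red blood cells, meninges and fibroblasts, pituitary hormones, and striatal, thalamic, cortical and hippocampal projection, hippocampal, hypothalamic, midbrain monoamine and amygdala markers. Some genes stand on several lists. Lists were tested across regions with camera at its preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists, for members with complete values. The list test of the high minus low difference was added later. In a single region and dose, a list's median was ranked among 10000 random lists of the same size and similar intensity. Named genes were the 10 largest rises and 10 largest falls over both doses among genes that passed in the same direction in all 6 regions, the 3 largest each way for each dose and for the dose difference, and the 2 largest each way for each region against the others. Of the genes for the dose difference, 1 is not reported here but stays in every test and count. They further included up to 3 genes each way that passed 1.5-fold in all 4 arrays of a region, up to 4 members of each list and the NMDA receptor subunits.

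The labels number the arrays 1 to 4 in every region, and the number gives the dose and the dye orientation. Deviations of the arrays with MK-801 in Cy5 from the mean of their dye swap correlated between groups (median 0.658, lowest 0.516, highest 0.842). The 66 pairs of groups held pairs within and across doses, so arrays pair through the dye orientation. A fit to single arrays with the dye orientation as a block and region as a random term is given beside the values it changed. Among the counts and named genes it was run on, it changed no other call.

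The tests were checked on simulated data. Random values for the 20725 complete genes, with each gene's own spread and dye effect, were given 200 changed genes, 50 for each size. Of the 50 planted at 1.5-fold, 50 were recovered over both doses, at the high dose and at the low dose, 47 in the high minus low difference and 36 in the region test with 1 changed region. At 1.2-fold the recovered numbers were 50, 49, 48, 36 and 1. False calls were 12 of 212, 14 of 213, 15 of 213, 9 of 191 and 8 of 141. The noise was drawn apart for every array, while the real regions share rats and the real doses share saline rats. False calls from differences between sets of rats were therefore not checked. Alternatives tried were no background correction, the scanner software's ratios, the series' value table, median centring, no filter and a strict filter on dim probes, the mean over a gene's probes, leaving out each array number and each region, another prior in eBayes, no dose covariate, other fold thresholds, the estimated correlation, and fits to single arrays. Added after the data were seen were scan day as a block, values within a scan day, removal of the remaining dye effect, leaving out blood, choroid plexus, meningeal and RT1 genes, leaving out the midbrain high dose swap, and genes with all 6 values only.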

Results

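Gene expression was measured in 6 brain regions of male rats 40 min after an injection of MK-801, a blocker of the NMDA receptor channel, or of saline. Each of the 24 two-colour arrays set RNA of MK-801 rats against RNA of saline rats. The design held 12 dye swaps of 2 arrays, 1 for each region and dose, with 0.16 mg per kg as the high dose and 0.08 mg per kg as the low dose. Values are log2 ratios of MK-801 to saline, given as mean ± SD over n regions, and every n counts regions of the same 9 rats. Between 56.3% and 79.1% of the probes of an array were well above background in both colours, and 23468 genes or transcripts were measured. Single regions at a single dose have 1 dye swap and therefore no error.

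In the saline RNA, markers set some of the dissected regions apart more clearly than others. All 14 measured striatal neuron markers were highest in the ventral striatum, and Drd1, a dopamine receptor, was 3.40 log2 units above the next region there. In the midbrain, 7 of 9 monoamine neuron markers were highest, among them Th, the first enzyme of dopamine synthesis, by 4.73 log2 units and Tph2, the enzyme of serotonin synthesis in neurons, by 1.38. Pmch, the melanin-concentrating hormone, and Oxt, oxytocin, were highest in the hypothalamus, by 3.13 and 1.55 log2 units. Avp, the vasopressin gene, was highest in the amygdala samples, by 1.93 log2 units. Of the hypothalamic neuropeptide genes, 3 of 15 were highest in the hypothalamus, and 8 of the 11 markers of cortical and hippocampal projection neurons were highest in the hippocampus. There, 5 of 8 hippocampal markers were highest. Of 9 amygdala and subcortical markers, 2 were highest in the amygdala, 3 in the hippocampus and 2 in the ventral striatum.

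The first comparison asked which genes differed from saline across the brain when both doses were averaged. Ccn1, a secreted matrix protein and early response gene, rose to 4.31-fold (log2 2.11 ± 1.37, n = 6, adjusted p = 0.0119, limma). Apold1, an early response gene of the endothelium, rose by 1.46 ± 0.80 (adjusted p = 0.00401), and Btg2, an inhibitor of cell proliferation, by 0.98 ± 0.58 (adjusted p = 0.00647). Dusp1, a phosphatase that switches off MAP kinases, rose by 0.84 ± 0.31 (adjusted p = 0.000302). Klf2, a transcription factor of the endothelium, rose by 0.64 ± 0.30, and Abcg2, an efflux pump of the blood-brain barrier, by 0.62 ± 0.10 (adjusted p = 3.98e-06). Other rises were those of Depp1, a target of FOXO factors, by 0.66 ± 0.47, Rsf1, a chromatin remodelling factor, by 0.50 ± 0.12, Cebpd, a stress-induced transcription factor, by 0.47 ± 0.34, and Gadd45g, a growth arrest gene, by 0.43 ± 0.14.

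The largest fall over both doses was that of Galnt16, an enzyme that starts the addition of O-linked sugars to proteins, with a log2 ratio of -1.33 ± 0.12 (n = 6, adjusted p = 2.8e-08, limma). Genes of the rat major histocompatibility complex followed, namely RT1-CE3 with -0.57 ± 0.10, RT1-CE16 with -0.53 ± 0.10, RT1-A2 with -0.40 ± 0.12, RT1-CE2 with -0.40 ± 0.10 and RT1-S3 with -0.39 ± 0.09. Ptprj, a receptor tyrosine phosphatase, fell as well, with -0.56 ± 0.05 (adjusted p = 3.7e-07). Isg15 and Irf7, a ubiquitin-like protein and a transcription factor of the interferon response, had -0.41 ± 0.14 and -0.39 ± 0.05, and Trps1, a GATA-type transcription factor, had -0.37 ± 0.10. A second probe of Ccn1 showed 0.98, a second probe of Ptprj -0.16, a second probe of RT1-A2 -0.09 (0.05 at the low dose), a second probe of RT1-S3 -0.32, and the 2 other probes of Trps1 0.05 and -0.04.

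In all, 605 of 23088 genes tested passed over both doses, 327 higher and 278 lower than saline, against 3162 at an unadjusted p under 0.05. Of the 605, 550 had 1 direction in all 6 regions, and 18 passed 1.5-fold. Their median size was 0.15, against 0.02 for all genes. The count was 393 without the ventral striatum and 366 without the cortex, and 1171 in the fit to single arrays with the dye orientation as a block. With 1 array number left out, so that 1 of the doses kept only 1 dye orientation, it was between 3689 (without number 1) and 4750 (without number 4), with 4675 without number 2 and 4659 without number 3. Within the 3 scan days it was 81, 270 and 75. With an intensity trend and robust prior, the calls of Ccn1 (adjusted p = 0.185), Apold1 (0.12), Btg2 (0.145), Klf2 (0.0615), Depp1 (0.211) and Cebpd (0.217) ended. The calls of Depp1 and Cebpd also ended with the scanner's ratios, with the series' value table (adjusted p = 0.0833 and 0.108) and without the amygdala (0.0661 and 0.0665) or the ventral striatum (0.0584 and 0.0864), and that of Depp1 without the hippocampus (0.0637). Within scan day 1 the calls of Ccn1 (0.185), Depp1 (0.294) and Isg15 (0.0877) ended. Within scan day 3 those of Depp1 (0.155), Cebpd (0.128) and Trps1 (0.1685) ended.

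**Figure D1:**
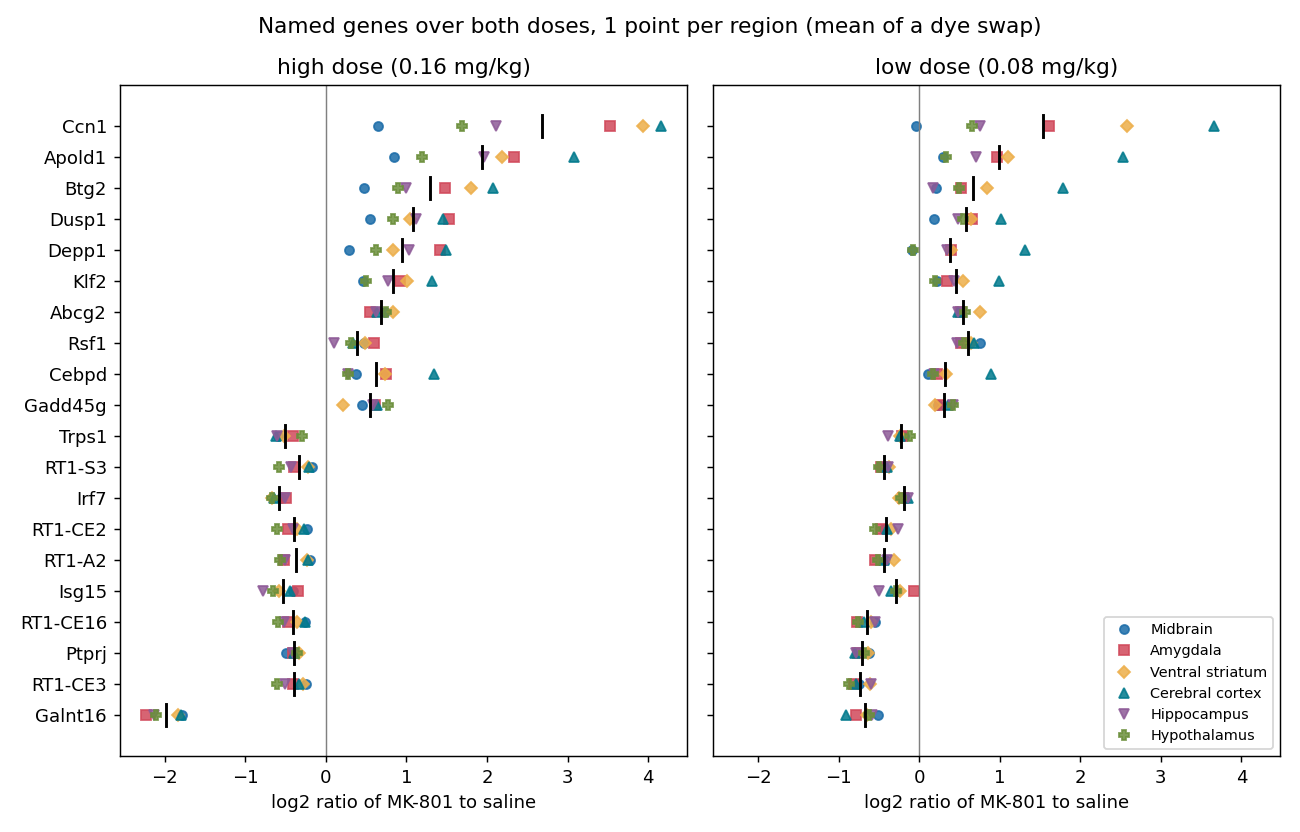
Log2 ratio of MK-801 to saline (x axis, log scale) of the 20 named genes over both doses (y axis), at the high dose on the left and the low dose on the right. Each point is 1 region, the mean of a dye swap, and the black bar is the mean of the 6 regions. Ccn1 spreads from 0.65 in midbrain to 4.16 in cortex at the high dose, while Galnt16 lies near -1.98 in every region.

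Of the gene groups, glucocorticoid and stress responsive genes rose most clearly over both doses. Of 17 measured, 10 rose and 0 fell (15 and 0 adjusted over the list alone, 15 at an unadjusted p under 0.05), with a median of 0.13. Besides Dusp1 and Cebpd, they included Sgk1, a kinase induced by glucocorticoids, by 0.54 ± 0.14 (n = 5), and Errfi1, an inhibitor of the EGF receptor, by 0.26 ± 0.06 (n = 5). The list stood out in camera (adjusted p = 9.69e-11) and kept an adjusted p = 0.0419 with an estimated correlation. Its direction was the same under each alternative scaling.

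Immediate early genes, which neurons and vessels switch on within minutes of a stimulus, went both ways over both doses. Of 30 measured, 7 rose and 3 fell (11 and 9 adjusted over the list alone), against 605 of all 23088 genes tested. Camera, which tests a net shift, did not call the 23 members with complete values (adjusted p = 0.58, median 0.02, mean 0.21). Ccn1, Btg2, Dusp1, Klf4 (0.88 ± 0.48, n = 5), Ier2, Sik1 and Fos rose. Egr2, Egr1 and Bdnf, the growth factor gene of activated neurons, fell, with -0.31 ± 0.14, -0.17 ± 0.13 and -0.15 ± 0.05 (n = 6, adjusted p = 0.00217, 0.0475 and 0.0051, limma). Atf3, a stress-induced transcription factor, had 0.87 ± 0.96 and did not pass (adjusted p = 0.141).

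The targets of the drug and most neuronal groups did not pass. None of the 7 measured NMDA receptor subunits passed in limma (1 at an unadjusted p under 0.05), and the largest value was that of Grin3a, 0.05 ± 0.05. Grin1, the subunit common to all NMDA receptors, had -0.02 ± 0.06, Grin2a -0.01 ± 0.05 and Grin2b -0.03 ± 0.05. The list's camera adjusted p was 0.987. By limma, 0 of 16 AMPA, kainate and metabotropic receptors, 0 of 17 GABA genes and 0 of 31 oxidative phosphorylation genes passed, with 2, 4 and 1 at an unadjusted p under 0.05. The same held for 0 of 35 ribosomal proteins, 0 of 13 heat shock genes and 0 of 11 choroid plexus markers, with 2, 3 and 0. Of the region markers, 0 of 14 striatal, 0 of 7 thalamic, 0 of 8 hippocampal, 0 of 9 midbrain monoamine and 0 of 9 amygdala genes passed, with 1, 1, 1, 0 and 1 at an unadjusted p under 0.05. Of 5 pituitary hormone genes and 4 red blood cell genes none passed in limma, with 0 and 0 at an unadjusted p under 0.05. The red blood cell list had a median of -0.01 and a mean of -0.02, with the camera direction up, and was not called (adjusted p = 0.987). In camera the choroid plexus list passed without the amygdala (adjusted p = 0.00335, mean -0.21). Without the cortex the GABA, heat shock, thalamic and projection neuron lists passed (adjusted p = 0.042, 0.00588, 0.042 and 0.0485, means -0.04, -0.08, -0.07 and -0.04).

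Of the lists of supporting cells, the oligodendrocyte and the meningeal list passed in camera over both doses, and the astrocyte, microglia and endothelial lists did not (adjusted p = 0.533, 0.0778 and 0.361). The microglia list passed without a filter on dim probes (adjusted p = 0.0348) and without the amygdala (0.0108), the cortex (0.035) or the hypothalamus (0.0415), with means of 0.04 to 0.05. The oligodendrocyte list was higher (camera adjusted p = 0.00237, median 0.08), with 1 of 14 members rising, Aspa, an enzyme that breaks down N-acetylaspartate, by 0.29 ± 0.12, and 4 adjusted over the list alone. The meningeal and fibroblast list was lower (camera adjusted p = 0.00335, median -0.14), with 1 of 12 falling, Slc6a13, a GABA transporter of the meninges, with -0.24 ± 0.19, and 3 adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.712 for each, with an estimated correlation). Neither list passed in fry (adjusted p = 0.478 and 0.551). The oligodendrocyte mean of 0.08 turned to -0.02 without array number 2 and was 0.02 without number 4, and the meningeal call ended without array number 1, 3 or 4 (adjusted p = 0.176, 0.112 and 0.0876), with the filter on all 24 arrays (adjusted p = 0.056) and without the hippocampus (adjusted p = 0.151, mean -0.07). Of 12 astrocyte markers 2 rose and 1 fell, Sox9, a transcription factor of astrocytes, with -0.29 ± 0.04 (n = 5). Of 12 endothelial and pericyte markers, Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.13 ± 0.04 and Kdr, a receptor of the growth factor VEGF, and Slco1c1, a thyroid hormone transporter, fell, with -0.24 ± 0.12 and -0.11 ± 0.07. Of 12 microglia markers, C1qc, a complement gene, rose by 0.14 ± 0.05. Among 11 projection neuron markers, Rasgrf2 rose by 0.27 ± 0.09, and among 15 hypothalamic peptides, Agrp fell, with -0.09 ± 0.04. In saline RNA the Agrp probe read 7.20 in the hypothalamus, the lowest region, and at most 7.79 elsewhere (log2 intensity). Its fall therefore rests on a probe that did not set the hypothalamus apart.

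At the high dose, Ccn1 rose to 6.4-fold (log2 2.68 ± 1.41, n = 6, adjusted p = 0.0028, limma; 1.29 by its other probe), Apold1 to 3.82-fold (1.93 ± 0.81) and Atf3 to 2.76-fold (1.46 ± 1.07, higher in 5 of 6 regions, adjusted p = 0.0237). Galnt16 fell to 0.253 of saline (-1.98 ± 0.20, adjusted p = 1.84e-08). P3h3, of a family of collagen-modifying enzymes, and Irf7 followed with -0.74 ± 0.11 and -0.59 ± 0.08, and another probe of P3h3 showed -0.04. Of 30 immediate early genes 10 rose and 1 fell (13 and 5 adjusted over the list alone), among them Klf4 by 1.12 ± 0.48, Nr4a1 by 0.61 ± 0.31 (n = 4), Fos by 0.55 ± 0.27 and Junb by 0.34 ± 0.26. The list was higher in camera (adjusted p = 0.000675), a call lost with an estimated correlation (adjusted p = 0.657 with an estimated correlation), and its median was 0.04 and its mean 0.37. Fry did not call this list (adjusted p = 0.243). Of 17 glucocorticoid responsive genes 12 rose and 0 fell (15 and 0 adjusted over the list alone), with Sgk1 at 0.63 ± 0.18 (n = 5) and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at 0.34 ± 0.11 (n = 5). Its camera adjusted p was 3.03e-15 (adjusted p = 0.104 with an estimated correlation). Of 4 red blood cell genes 3 rose (4 adjusted over the list alone), namely Hbb, a globin, by 0.33 ± 0.23, Alas2, the first enzyme of haem synthesis in red cells, by 0.30 ± 0.12, and Slc4a1, the red cell anion exchanger, by 0.18 ± 0.08. Camera gave adjusted p = 1.88e-06 (adjusted p = 0.166 with an estimated correlation).

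At the high dose 495 of 23326 genes passed, 266 higher and 229 lower, with 2800 at an unadjusted p under 0.05, and 453 had 1 direction in 6 regions. The count was 307 without the amygdala, 317 without the ventral striatum, 294 without the cortex and 680 with the dye orientation as a block, 150, 276 and 89 within the scan days, and 6627 without array number 1 and 7523 without number 2, where 1 dye orientation was left. Atf3 lost its call without the amygdala, ventral striatum, cortex or hippocampus (adjusted p = 0.0875, 0.0915, 0.0605 and 0.0686), with the scanner's ratios (0.124) and with the series' value table (0.129), and Ccn1, Apold1 and Atf3 lost theirs with an intensity trend and robust prior (adjusted p = 0.132, 0.0689 and 0.272).

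At the low dose, Ccn1 rose to 2.9-fold (log2 1.53 ± 1.38, n = 6, higher in 5 of 6 regions, adjusted p = 0.0477, limma; 0.66 by its other probe), Apold1 rose by 0.99 ± 0.82 (adjusted p = 0.0321) and Btg2 by 0.67 ± 0.60 (adjusted p = 0.0485). RT1-CE3 fell to 0.6 of saline (-0.74 ± 0.11, adjusted p = 9.67e-07), Ptprj had -0.71 ± 0.08 (-0.23 by its other probe) and Galnt16 -0.68 ± 0.14. Of 30 immediate early genes 3 rose, Ccn1, Btg2 and Dusp1, and 5 fell (5 and 7 adjusted over the list alone), Egr2, Egr1, Nr4a3, Egr4 and Bdnf, the first with -0.41 ± 0.17. The list showed no net shift against other genes in camera (adjusted p = 0.227, direction down, with a median of -0.01 but a mean of 0.07). Of 17 glucocorticoid responsive genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), with Dusp1 at 0.59 ± 0.27 and Sgk1 at 0.45 ± 0.10. Its camera adjusted p was 1.72e-08 (adjusted p = 0.0442 with an estimated correlation).

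Other lists also passed in camera at the low dose. Oligodendrocyte markers were higher (adjusted p = 4.45e-06, median 0.13, 2 of 14 rose, Aspa and Mag, and 7 adjusted over the list alone), and microglia markers were higher (adjusted p = 0.000286, median 0.06, 4 of 12 rose and 5 adjusted over the list alone), among them P2ry12, a purine receptor of resting microglia, by 0.17 ± 0.07 and C1qc by 0.22 ± 0.03. Lower were the red blood cell genes (adjusted p = 0.000165, median -0.31, 3 of 4 fell and 4 adjusted over the list alone), with Hbb at -0.54 ± 0.31 and Alas2 at -0.31 ± 0.19. Meningeal markers were lower too (adjusted p = 3.07e-06, median -0.25, 1 of 12 fell and 7 adjusted over the list alone), as were heat shock genes (adjusted p = 0.00696, median -0.04), where Hspa1a and Hspb1 fell, 2 of 13 (3 adjusted over the list alone), with -0.34 ± 0.28 and -0.20 ± 0.08. These 5 calls were lost with an estimated correlation (adjusted p = 0.329, 0.401, 0.329, 0.495 and 0.305, each with an estimated correlation). In fry the 5 lists had adjusted p = 0.0528, 0.0528, 0.0691, 0.317 and 0.0528 and did not pass.

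At the low dose 609 of 23328 genes passed, 301 higher and 308 lower, with 3105 at an unadjusted p under 0.05, and 557 had 1 direction in 6 regions. The count was 397 without the ventral striatum, 55, 118 and 211 within the scan days, and 8358 without array number 3 and 7254 without number 4. The calls of Ccn1, Apold1 and Btg2 sat near the threshold and each ended without the amygdala (adjusted p = 0.106, 0.0738 and 0.0843), the ventral striatum (0.17, 0.108 and 0.155) or the hippocampus (0.0784, 0.0759 and 0.0527). Those of Ccn1 and Btg2 also ended without the hypothalamus (0.066 and 0.0988), and that of Ccn1 without the cortex (0.0661, mean 1.11). The calls of all 3 ended with an intensity trend and robust prior (adjusted p = 0.334, 0.296 and 0.329), with the scanner's ratios (0.0997, 0.141 and 0.19) and with the series' value table (0.104, 0.145 and 0.196). Those of Ccn1 and Btg2 also ended without background correction (0.0514 and 0.055), with median centring (0.0645 and 0.0667), with the filter on all 24 arrays (0.0537 and 0.0543) and with probe means (0.0874 and 0.0531).

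The doses shared a part of their genes. Of 23239 genes tested at both, 495 passed at the high and 607 at the low dose, 204 passed at both where 12.9 would be had with independent calls, and 181 of the 204 had the same direction, 97 up and 84 down. Both doses were set against the same 3 saline rats, so calls at the doses are not independent and 12.9 is no level for unchanged genes.

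**Figure D2:**
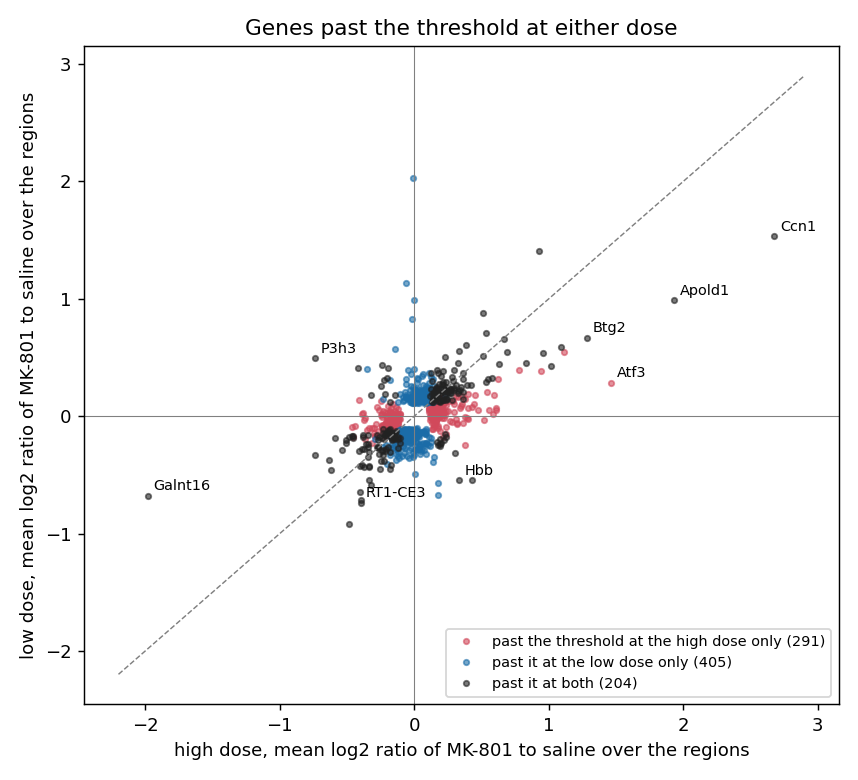
Mean log2 ratio of MK-801 to saline over the regions at the high dose (x axis) and the low dose (y axis) for genes past the threshold at either dose, 1 point per gene, coloured by the dose at which it passed. The dashed line marks equal change. Ccn1, Apold1 and Btg2 lie to the right of the line, with larger rises at the high dose, and Galnt16 lies at -1.98 and -0.68.

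The next comparison asked which genes responded differently to the 2 doses. Immediate early genes were higher at the high than at the low dose. Of 30 measured, 14 were higher and 0 lower (18 and 0 adjusted over the list alone, 18 at an unadjusted p under 0.05), with a median difference of 0.17. Atf3 differed by 1.18 ± 0.64 (n = 6, adjusted p = 0.0023, limma), Ccn1 by 1.15 ± 0.51 (adjusted p = 0.000572), Klf4 by 0.65 ± 0.14 (n = 5), Btg2 by 0.62 ± 0.34, Dusp1 by 0.50 ± 0.22 and Fos by 0.50 ± 0.30. Each of these was higher at the high dose in every region with a value. For Egr1 the higher value was a smaller fall, -0.09 at the high and -0.26 at the low dose. The list's camera adjusted p was 4.35e-13 (adjusted p = 0.0572 with an estimated correlation), and fry gave an adjusted p of 0.0105.

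Some genes moved in opposite directions at the doses. Haus1, part of a complex that branches microtubules, was 0.97 ± 0.12 higher at the high dose (0.43 at the high and -0.54 at the low dose), and its other probe showed the opposite, -0.16 and 0.30. P3h3 differed by -1.19 ± 0.12 (n = 5, -0.74 and 0.49), and its other probe showed -0.04 and 0.01, so the opposite directions of both genes rest on 1 probe each. Galnt16 was lower at both doses and differed by -1.31 ± 0.25. Of 4 red blood cell genes 3 were higher at the high dose, Hbb by 0.88 ± 0.26, Alas2 by 0.61 ± 0.09 and Slc4a1 by 0.26 ± 0.15 (camera adjusted p = 1.12e-11, adjusted p = 0.0572 with an estimated correlation, 3 adjusted over the list alone). Of 17 glucocorticoid responsive genes 4 were higher (5 adjusted over the list alone), Dusp1, Cebpd, Mt1 and Sgk1 (camera adjusted p = 6.16e-05, adjusted p = 0.369 with an estimated correlation). Of 12 microglia markers 3 were lower at the high dose (5 adjusted over the list alone), P2ry12, C1qc and C1qa (camera adjusted p = 0.000245, adjusted p = 0.369 with an estimated correlation). Meningeal markers had a median difference of 0.20, and 0 of 12 passed in limma, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.000106, adjusted p = 0.698 with an estimated correlation). Fry called the red blood cell and microglia lists (adjusted p = 0.00219 and 0.0176), and not the glucocorticoid and meningeal lists (0.12 and 0.577).

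In all, 351 of 23088 genes differed between the doses, 205 higher and 146 lower at the high dose, with 2494 at an unadjusted p under 0.05, and 314 had 1 direction in 6 regions. The count was 65, 127 and 52 within the scan days, and between 5367 (without array number 4) and 7444 (without number 3), with 5793 and 5921 without numbers 1 and 2. It was also lower with the scanner's ratios, the series' value table and median centring, as given in the closing section. The call of Ccn1 ended in the fit with the dye orientation as a block (adjusted p = 0.285) and with an intensity trend and robust prior (adjusted p = 0.092). That of Atf3 ended with the scanner's ratios (adjusted p = 0.0567), the series' value table (0.06), that prior (0.164) and within scan day 1 (0.226).

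The third question was which genes responded differently between brain regions. P values here measure the spread between the doses of a region, which share a slide and the same saline rats. The response of Ccn1 was largest in the cerebral cortex, at 4.16 and 3.66 for the high and low dose, and smallest in the midbrain, at 0.65 and -0.04. Its contrast with the other regions was 2.17 in the cortex, 1.38 in the ventral striatum, -1.12 in the hypothalamus and -2.16 in the midbrain (adjusted p = 0.000152, 0.00848, 0.0177 and 5.27e-05, limma). Atf3 stood at 2.87 and 2.16 in the cortex (contrast 1.97, adjusted p = 0.0011) and at -0.10 and -0.35 in the midbrain (contrast -1.32, adjusted p = 0.0178). Jun, a part of the AP-1 factor, and Adamts1, a secreted protease, were lower in the hippocampus than elsewhere (contrasts -0.42 and -0.40, adjusted p = 0.0401 and 0.0402). Sox18, a transcription factor of the endothelium, was lowest in the cortex, at -0.86 and -0.57 (contrast -0.53, adjusted p = 0.000816), and Pdgfrl, a gene similar to growth factor receptors, was lower there too (contrast -0.42, adjusted p = 0.0368).

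Genes of peptide and monoamine neurons differed in single regions. Avp was at -1.91 and -1.70 in the amygdala and Oxt at -0.98 and -1.06 (contrasts -1.74 and -1.04, adjusted p = 1.26e-07 and 0.00186, limma). Pmch was at -2.96 and -1.76 in the hypothalamus (contrast -2.31, adjusted p = 6.85e-05). Tph2 was at 0.77 and 1.42 in the midbrain (contrast 1.01, adjusted p = 4.07e-05), as was Epyc, a small proteoglycan, at 0.69 and 0.99 (contrast 0.86, adjusted p = 1.38e-05). Sostdc1, a secreted inhibitor of bone morphogenetic proteins made in choroid plexus, and Steap1, a membrane protein, were higher in the amygdala (contrasts 1.42 and 0.79, adjusted p = 0.0469 and 0.0238), where the whole choroid plexus list was higher. Their F tests over all regions did not pass (adjusted p = 0.0587 and 0.0562), nor did that of Pdgfrl (0.0522). In the ventral striatum Avp was at 0.18 and -0.15, and its contrast of 0.45 (adjusted p = 0.0368) is set against a mean that holds the low amygdala value. Cfap144, a gene of cilia, and Trim54, a gene of the cytoskeleton, were lower there (contrasts -0.76 and -0.73, adjusted p = 0.0208 and 0.000166). Srp68, of the signal recognition particle, was higher in the hippocampus (contrast 0.36, adjusted p = 0.0258), and Pygl, a glycogen phosphorylase, and Sdc1, a cell surface proteoglycan, in the hypothalamus (contrasts 0.40 and 0.38, adjusted p = 0.0163 for both).

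By the F test, 253 of 20725 genes differed between regions. The contrasts called 222 genes in the amygdala (145 higher, 77 lower), 112 in the midbrain (22 and 90), 73 in the hypothalamus (26 and 47), 33 in the ventral striatum (6 and 27), 32 in the cortex (24 and 8) and 26 in the hippocampus (3 and 23). The F count was 168 without the midbrain, 133 without the ventral striatum, 116 without the hypothalamus, 114, 54 and 48 without array numbers 1, 2 and 4, and 522 with the dye orientation as a block. It was 75 without the dose covariate and 899 with an intensity trend and robust prior. With the scanner's ratios, the series' value table or median centring the F count fell further still, as given in the closing section. Between the 2 regions of each scan day it was 415, 26 and 78.

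Within single regions and doses, genes past 1.5-fold on both arrays were counted without a test. The counts hold every such difference from saline, and differences in the dissected tissue were not separated from a response to the drug. At the high dose the amygdala had 42 genes higher and 4 lower than saline, against 3 in opposite directions on the 2 arrays. The cortex had 28 higher and 7 lower at the high dose and 23 and 38 at the low dose, against 2 and 3. The ventral striatum had 18 and 10 at the high dose and 9 and 8 at the low dose, against 3 and 9, the hippocampus 10 and 14, then 9 and 10, against 4 and 11, and the hypothalamus 14 and 18, then 5 and 9, against 2 and 0. The amygdala at the low dose had 10 and 9, against 5. In the midbrain, 12 and 7 genes at the high dose and 11 and 16 at the low dose stood against 61 and 26 in opposite directions, more than passed at the high dose. Over the 12 dye swaps, 341 passed (191 higher, 150 lower) against 129 in opposite directions. The order of the regions depended on the scaling and the threshold. With the scanner's ratios the high dose gave 133 genes in the hippocampus, 129 in the midbrain, 105 in the ventral striatum, 103 in the hypothalamus, 97 in the amygdala and 75 in the cortex. Past 2-fold, with the loess-normalized ratios used throughout, the high dose gave 18 in the cortex and 17 in the amygdala. The total was 1082 with the scanner's ratios, 191 with median centring and 103 past 2-fold, and leaving out 1 array number gave 978 to 1113.

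**Figure D3:**
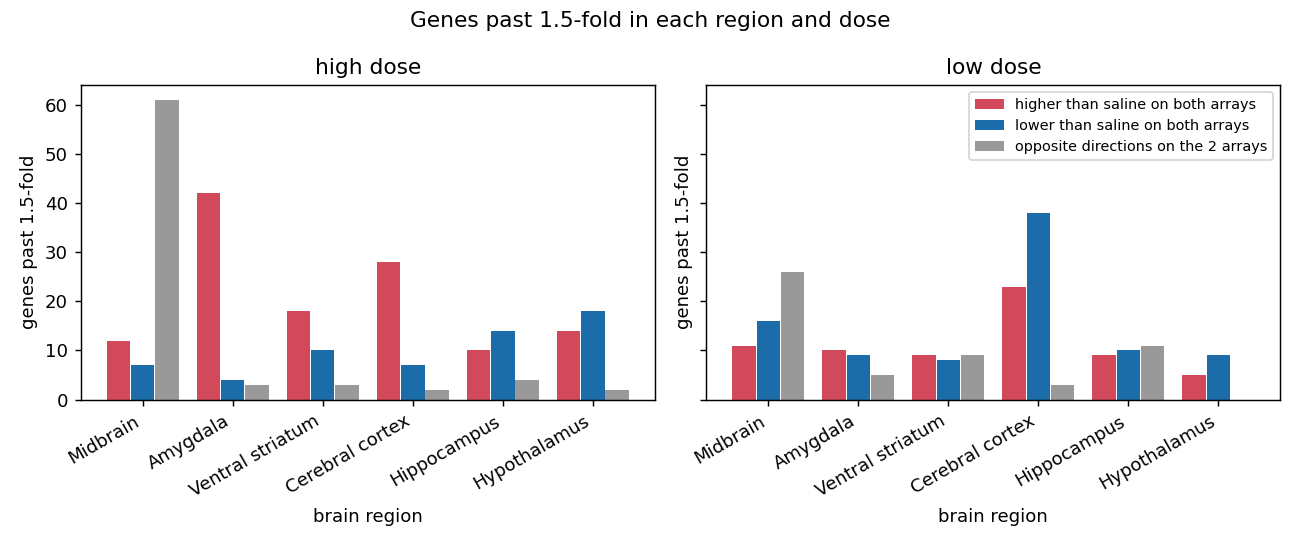
Number of genes past 1.5-fold (y axis) in each brain region (x axis), at the high dose on the left and the low dose on the right. Bars give genes higher than saline on both arrays, lower on both arrays, and past the threshold in opposite directions on the 2 arrays. The amygdala at the high dose has 42 genes higher and 4 lower, and the midbrain has 61 in opposite directions.

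Few genes passed 1.5-fold on all 4 arrays of a region, and up to 3 each way are named per region. Ccn1 did so in every region but the midbrain and the hypothalamus, with a smallest array value of 3.56 in the cortex, 2.37 in the ventral striatum, 1.56 in the amygdala and 0.68 in the hippocampus. Apold1 followed in the cortex, ventral striatum and amygdala with 2.33, 0.92 and 0.73, Atf3 in the cortex with 1.97 and Btg2 in the ventral striatum with 0.83. The cortex had 17 genes higher and 2 lower, among the latter Galnt16 with -0.91, which was also lower in the amygdala with -0.60. Slc6a4, the serotonin transporter, was the gene higher in the midbrain, with 0.63, and Prkcd, a protein kinase C of thalamic and amygdala neurons, and Ptpn3, a tyrosine phosphatase, were lower there, with -0.85 and -0.68. In the amygdala Avp and Oxt had -1.63 and -0.85. In the hippocampus Ttr, the thyroxine carrier of the choroid plexus, had -2.06, Sostdc1 -0.94 and Col3a1, a fibrillar collagen, -0.62. In the hypothalamus Pmch had -1.74, Th -0.93 and Slc18a2, the vesicular monoamine transporter, -0.73. The counts higher and lower were 1 and 3 in the midbrain, 4 and 3 in the amygdala, 5 and 0 in the ventral striatum, 2 and 7 in the hippocampus and 1 and 4 in the hypothalamus.

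Gene lists also differed between single regions, described without a test. Glucocorticoid and stress responsive genes lay on the high side of random lists in 10 of 12 regions and doses, with medians up to 0.28 in the midbrain at the high dose. Immediate early genes lay on the high side at the high dose in the cortex (0.13), amygdala (0.08), hippocampus (0.06) and hypothalamus (0.06), and on the low side at the low dose in the ventral striatum (-0.06) and midbrain (-0.04). Red blood cell genes lay on the high side in all 6 regions at the high dose and on the low side in 5 at the low dose. Choroid plexus markers had a median of 0.89 in the amygdala at the high dose, 8 of 8 members above 0, and of 0.20 at the low dose. They had -0.17 and -0.37 in the hippocampus, and -0.46 and 0.07 in the hypothalamus. Meningeal markers had 0.43 and -0.21 in the midbrain, -0.40 and -0.51 in the hippocampus and -0.79 in the cortex at the low dose. Thalamic markers had -0.23 and -0.29 in the midbrain, striatal markers -0.17 and -0.20 in the hypothalamus and 0.09 and 0.12 in the amygdala. Oligodendrocyte markers lay on the high side in 7 of 12 regions and doses, with 0.18 and 0.14 in the midbrain, and on the low side in the hypothalamus at the high dose (-0.11). Of 276 list, region and dose values, 92 lay outside the central 95% of random lists, where 13.8 would be had by chance for independent genes.

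**Figure D4:**
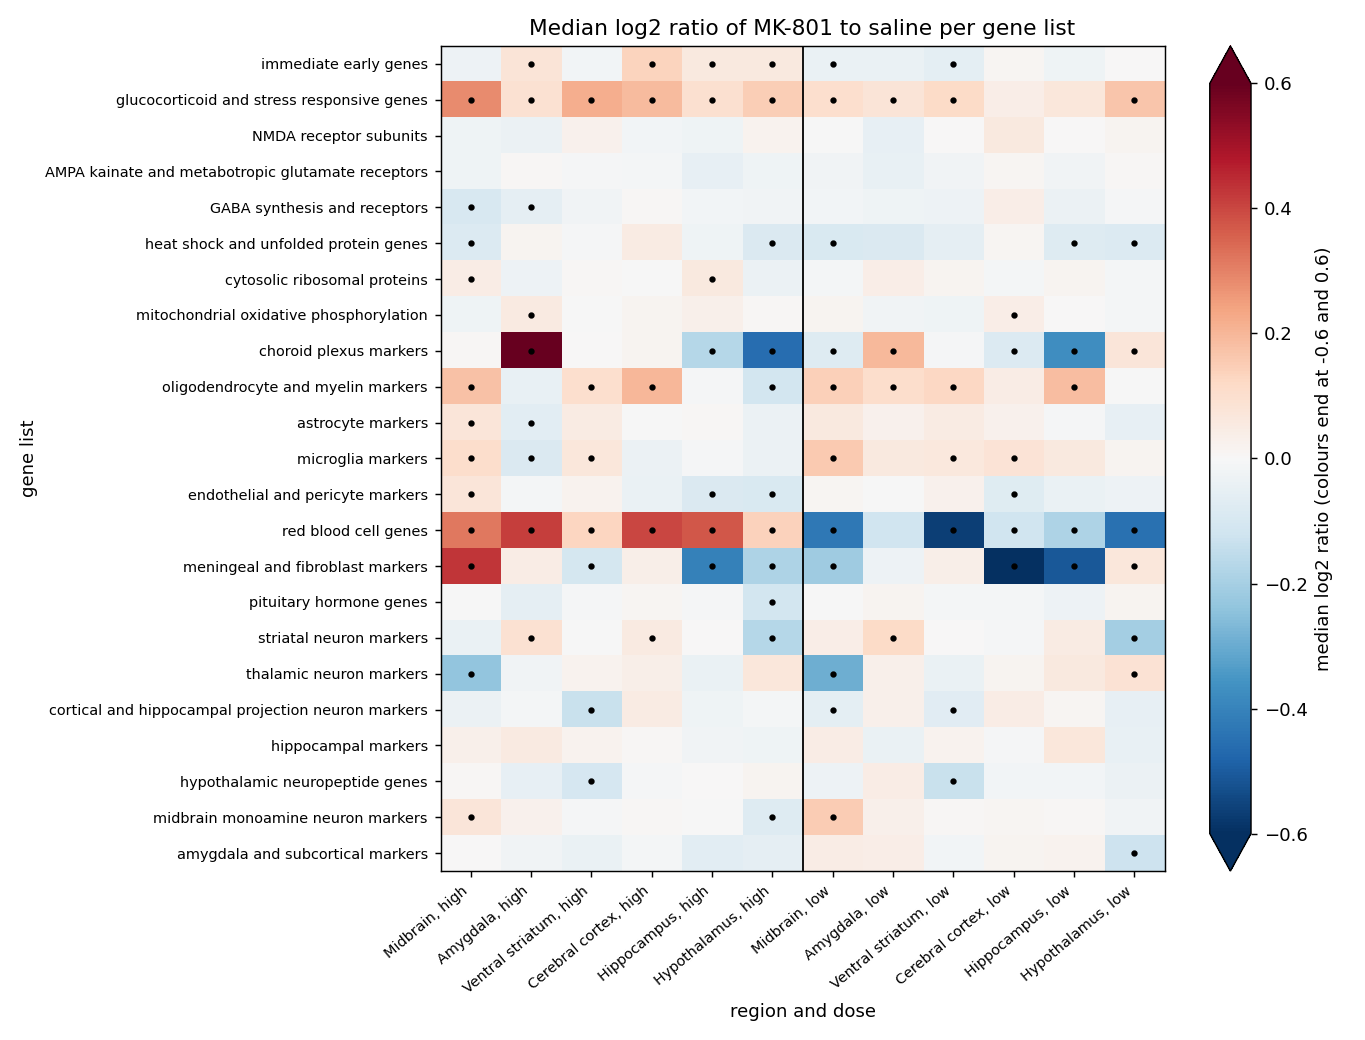
Median log2 ratio of MK-801 to saline (colour, ending at -0.6 and 0.6) of each gene list (y axis) in each region and dose (x axis), with the high dose left of the line. Dots mark medians outside the central 95% of random lists of the same size and similar intensity. Choroid plexus markers reach 0.89 in the amygdala at the high dose, and red blood cell genes are above 0 in 6 regions at the high dose.

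The series states expression patterns along chromosomes as an aim, so genes past 1.5-fold were counted per chromosome. Chromosome 4, which carries Apold1, Depp1, Abcg2 and P3h3 on assembly rn3, held 36 of 14837 gene values past 1.5-fold over the 12 dye swaps, or 0.243%. Chromosome 1, which carries Rsf1 and Irf7, held 31 of 31565, and chromosome X 0 of 9301. In Fisher's exact tests of each chromosome, region and dose, 0 of 252 passed adjustment (smallest adjusted p = 1), with 8 at an unadjusted p under 0.05 and a smallest exact p of 0.0137, for chromosome 4 in the ventral striatum at the high dose. Genes are not independent replicates, so these tests describe the arrays. Expected counts per test were only 0.28 to 6.62, so the tests had little power. For chromosome X at most 1.94 genes were expected in a test, and its smallest unadjusted p was 0.267 (Fisher's exact test). A lack of such genes on it could not pass in these tests.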

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

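Chosen only after the results were seen were the tests of remaining dye bias, of differences between the rats, of Alas2, of vessel tissue, of dissection borders and of a regional drug response. The others were written before, though the test of white cell and platelet genes concerns a pattern that was known only from the results.

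Across the 6 regions, 605 genes passed over both doses, 495 at the high dose, 609 at the low dose and 351 between doses, and turning the signs of regions in the 31 other ways gave at most 4, 3, 1 and 3, with 1 of 32 sign patterns reaching each real count. The regions came from the same rats, so their signs are not independent, and this does not exclude chance differences between rats. Single dye swaps correlated with the mean dye effect by -0.194 to 0.207, but the change over both doses did so by only -0.0013. Regressing it out of each swap could therefore end few calls, and 97.52% of the genes (590 of 605) were still called. The change over both doses thus did not follow the mean dye effect, and other dye bias was not tested. Of the 605, 48.1% changed more at the high dose, against 48.7% of all genes, so the set as a whole showed no larger change there. Any deviation of the shared saline rats enters both doses alike and weakens this comparison. The share therefore does not exclude a drug response that grows with the dose. Differences between the few rats of each group may account for much of the change across genes. Over the 20725 genes with complete values, the covariance between regions across doses was 0.535 of that within a dose (0.433 to 0.602 with 1 region left out). That is near the 0.5 that 3 sets of rats sharing the saline set give. The ratio was not computed for the 605 alone, and a response shared only in part by the doses could give it as well. Of 30 immediate early genes 14 were higher at the high dose and 0 lower, though the list's call was lost with an estimated correlation (adjusted p = 0.0572), and how far rats of a group differ stays open because no array is assigned to an animal.

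Red blood cell genes were above saline at the high dose and below it at the low dose, with a median difference of 0.61 between doses. More vessel tissue at the high dose is argued against, since the endothelial and pericyte list differed by a median of 0.0173 (0.00894 to 0.0277 with 1 region left out). Blood left in the tissue may account for it: the platelet gene Pf4 differed by 0.386 (0.345 to 0.449 with 1 region left out). Pf4 was the only measured one of 4 white cell and platelet genes. It had 0.32 at the high dose but -0.07 at the low dose, where Hbb had -0.54, Alas2 -0.31 and Slc4a1 -0.09. Pf4 therefore went mainly with the rise at the high dose and says little about the values below saline. The haem gene Alas2 differed by 0.612 (regions 0.522 to 0.717), but it belongs to the red blood cell list and gave the list's median. Alas2 therefore adds no separate support. A change in the blood cells themselves was not tested.

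Between regions, 253 genes differed, and these included 23 of 130 region and cell type markers, an odds ratio of 19.0 (95% interval 11.3 to 30.7, Fisher's exact test), so different dissection borders may account for a part. They also included 9 of 23 immediate early genes, an odds ratio of 53.8 (20.3 to 135), so a drug response that differs between regions may account for another part. Neither test covers the genes outside these lists. Region, slide and saline RNA cannot be told apart, because each region lay on its own slide.

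Cebpd over both doses was 1.12 in the cortex, far from the 0.22 to 0.53 of the other regions. Apold1 at the low dose was 2.53 in the cortex, far from 0.30 to 1.10 elsewhere. Of 38 sets of regional values tested, 2 had such a region, where chance gives 1.9. Between the doses, the test of the difference passed for Atf3 (1.18), Ccn1 (1.15), Haus1 (0.97), Galnt16 (-1.31) and P3h3 (-1.19). The call of Ccn1 ended with the dye orientation as a block, and those of Ccn1 and Atf3 with an intensity trend and robust prior. Those of Haus1 and P3h3 rest on a single probe each. Of the lists, the median difference between doses was 0.17 for immediate early genes, 0.0887 for glucocorticoid and stress responsive genes, -0.0529 for microglia markers, 0.61 for red blood cell genes and 0.20 for meningeal and fibroblast markers, and these 5 calls in camera were lost with an estimated correlation (adjusted p = 0.0572, 0.369, 0.369, 0.0572 and 0.698). Against the other regions, the midbrain differed for Tph2 (1.01), Epyc (0.86), Ccn1 (-2.16) and Atf3 (-1.32). The amygdala differed for Sostdc1 (1.42), Steap1 (0.79), Avp (-1.74) and Oxt (-1.04). The ventral striatum differed for Ccn1 (1.38), Avp (0.45, against a mean that holds the low amygdala value), Cfap144 (-0.76) and Trim54 (-0.73). The cortex differed for Ccn1 (2.17), Atf3 (1.97), Sox18 (-0.53) and Pdgfrl (-0.42). The hippocampus differed for Srp68 (0.36), Jun (-0.42) and Adamts1 (-0.40). The hypothalamus differed for Pygl (0.40), Sdc1 (0.38), Pmch (-2.31) and Ccn1 (-1.12).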

How the results depend on the processing

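Scan day as a block, values within a scan day, removal of the remaining dye effect, leaving out blood, choroid plexus, meningeal and RT1 genes, leaving out the midbrain high dose swap, and genes with all 6 values only were alternatives chosen after the data were seen. Of the counts under alternatives, 109 stayed within 1.5 times the reported count and 73 moved further. Of the named genes, those for both doses, each dose and the dose difference were run under alternatives. Their calls reversed in no alternative, and stayed past the threshold in 335 values with arrays or regions left out and 552 others. Against these stood 21 and 51 that no longer passed, most of them of Ccn1, Btg2, Apold1, Depp1, Cebpd and Atf3. The contrasts of named genes between regions, and genes named only as list members, were not run under alternatives. No chromosome passed by Fisher's exact test in the 12 alternatives it was run on, which leave out the 0.75 threshold and the fit to single arrays. The median signal was 1.82 to 3.1 times background in Cy3 and 3.23 to 5.77 times in Cy5, so small ratios of dim genes were measured with little precision. Over single genes, lists and regions, 1374 values stayed the same, 97 moved, 79 were weaker, 9 stronger and 2 reversed.

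The counts over both doses, at the high dose, at the low dose and between doses, reported as 605, 495, 609 and 351, were 341, 273, 329 and 197 with the scanner software's ratios, 328, 262, 319 and 194 with the series' value table and 333, 135, 357 and 98 with median centring only. Of the 605, 313, 302 and 315 were shared. The count between regions, reported as 253, was 14, 12 and 43 in the same alternatives, 149 without a filter on dim probes, 75 without the dose covariate and 899 with an intensity trend and robust prior. For each, the cause was not tested. With the dye orientation as a block, 1171 genes were called over both doses (564 shared with the 605) and 522 between regions. The genes past 1.5-fold, 341 in all, were 1082, 1175 and 191 in those 3 alternatives, 103 at 2-fold, 569 with a lower threshold of 0.75 for falls, and 2769 in a fit to single arrays with 12 coefficients, whose p values measure only the spread within dye swaps.

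Leaving out arrays or regions in turn gave 366 to 4750 genes over both doses, 294 to 7523 at the high dose, 397 to 8358 at the low dose, 237 to 7444 between doses, 48 to 328 between regions, 978 to 1113 past 1.5-fold and 1 to 8 lists, where 3 lists were reported. Over both doses, at each dose, between doses and past 1.5-fold, the largest counts were those with 1 array of a swap left out, where by construction the dye effect does not cancel, and whether it made up the added genes was not tested. Between regions the largest count, and the largest number of lists, arose without the cortex. Camera with an estimated correlation called 1 list. The mean of the oligodendrocyte list was -0.0151 to 0.181 with arrays or regions left out, and it turned its direction against other genes without array number 2 (mean -0.0151) and without number 4 (mean 0.0153). Within scan days 1, 2 and 3, each with 2 regions, the counts were 81, 270 and 75 over both doses, 150, 276 and 89 at the high dose, 55, 118 and 211 at the low dose, and 65, 127 and 52 between doses. With scan day as a block they were 450, 437, 423 and 307, and between the 2 regions of a day 415, 26 and 78 genes differed. Scan day as a block cannot be fitted to differences between regions, since each region was scanned on 1 day.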

Other observations

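Interferon-induced genes, a group chosen after the values were seen, lay below saline together. Of 18 measured, 8 fell and 0 rose over both doses, 7 and 0 at the high dose and 5 and 0 at the low dose, with a median of -0.11 over both doses. At the high dose their median was -0.13, and 6 were lower at the high than at the low dose and 0 higher. Of the RT1 genes of the major histocompatibility complex, also chosen after their values were seen, 24 were measured, and 11 fell and 2 rose over both doses (median -0.10). Those that rose were RT1-CE10, by 0.25, and RT1-N1, by 0.17. Between doses 2 RT1 genes were higher and 1 lower at the high dose. Whether RT1 probes bind several members of the family was not tested.

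Random values with no difference between the groups, but with the same saline values behind both doses, gave a correlation across genes of 0.5003 between the dose changes, the mean of 20 simulations, against 0.463 in the data. The covariance was 0.00207 in the data and 0.000702 in the simulations (highest 0.000783). No gene was called at both doses in these simulations, against 187 of the 20725 complete genes in the data. The simulations drew each region on its own, while the real regions came from the same rats. Neither the 0 nor the simulated covariance is therefore a level for unchanged genes in this design. The simulated correlation follows by construction from the shared saline values, so its nearness to the data decides nothing about the cause.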
